A study of Mus musculus with 4 samples.

How the data were processed

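The study covers 4 single-cell libraries of mouse bone marrow cells (10x Chromium 3' v3.1 chemistry, Illumina NovaSeq). Per the labels, the mice were of the C57Bl/6JCrl background, received tamoxifen by 5 intragastric doses at 7 to 8 weeks of age and were irradiated with 4 Gy 2 weeks later where irradiated. VE-cadherin antibody was injected into the circulation before the marrow was taken, tibial marrow was digested with collagenase I, dispase II and DNase I, and viable cells negative for lineage markers, CD45 and Ter119 were sorted. Each group has 1 library, from 3 pooled mice without and 2 pooled mice with irradiation.

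The deposited files hold raw UMI counts per gene and cell barcode, as whole numbers without normalization, over 31053 features that were the same in all libraries. The submitters' processing notes name Cell Ranger 2.1.1 and the mm10 build, whereas the matrix header records software 3.1.0. The annotation release and the cell-calling options are not given in the sources used here. Barcodes had at least 500, 500, 500 and 501 UMIs (non-irradiated control, non-irradiated Vegfc-deleted, irradiated control, irradiated Vegfc-deleted). The labels state tamoxifen for part of the samples in 1 place and for both genotypes in another, and give 3 irradiated mice per genotype in 1 place and 2 pooled in another. Which part of Vegfc is deleted is not given in the sources used here. Because 3' tags need not lie in a deleted part, its level was measured rather than assumed.

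The libraries held 7454, 7737, 5150 and 5134 barcodes. Those with fewer than 500 genes or more than 10% mitochondrial UMIs were left out (2071, 2200, 1175 and 895). Doublets were scored per library with Scrublet in scanpy 1.11.5, and the highest-scoring barcodes were left out at a rate of 0.8% per 1000 barcodes, that is 444, 479, 212 and 211 barcodes (5.96%, 6.19%, 4.12% and 4.11%). Kept cells had medians of 2242.5, 2245, 3125 and 2636 genes. Counts were scaled per cell and log-transformed, 2000 variable genes were reduced to 40 principal components, and a shared graph of 20 nearest neighbours was clustered with Leiden (leidenalg 0.10.2, igraph 0.11.9, resolution 1, seed 7) over all libraries together, without batch correction. This gave 37 clusters.

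Clusters were named from 20 fixed marker lists by the mean log2 ratio of marker CPM to the median over clusters. A name required a score of at least 2, a margin of 1 over other compartments, 3 detected markers and a marker of its own among the 10 leading genes. No cluster was named arterial endothelium, chondrocyte, fibroblast, Schwann cell, skeletal muscle or haematopoietic progenitor, and 5 clusters stayed unnamed (0.811%, 0.537%, 8.86% and 3.91% of kept cells). The smaller named classes were megakaryocytes (2.79%, 2.67%, 2.84% and 0.836%), dendritic cells (0.158%, 0.883%, 0.313% and 2.44%), plasma cells (0.297%, 0.614%, 0.625% and 1.89%) and pericytes or smooth muscle (0.356%, 0.307%, 0.391% and 0.172%). The endothelial class joined all endothelial clusters (308, 376, 1500 and 706 cells), of which 300, 351, 1385 and 662 cells were sinusoidal. The LepR+ stromal class held 1202, 749, 428 and 143 cells.

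Counts were summed per class and library and expressed as UMIs per 1000000 of the class (CPM). Shares carry exact (Clopper-Pearson) binomial intervals, CPM exact Poisson intervals and ratios exact conditional intervals, all at 95%. Log2 ratios of genes used a prior of 0.5 counts. A fold against 0 counts is given as the lower limit of its interval, and list medians were also computed with 0 counts set at a floor of 3. Response was read in 20 gene lists fixed before the data were examined, on VEGF ligands and receptors, haematopoietic niche factors, p53 targets, cell cycle, interferon response, inflammation and adhesion, antigen presentation, adipogenic, osteogenic, endothelial junction and barrier, sinusoidal, arterial and sprouting endothelial identity, extracellular matrix, immediate early and dissociation, oxidative stress, hypoxia and glycolysis, apoptosis, TGF-beta and BMP response, and free haemoglobin and granule RNA. For 2 list genes (Ccl19 and Aldoa) no feature of that name was found. Each list gave a median over genes with a summed count of at least 10 and a percentile among 10000 random lists matched on expression in 20 bins, which describes these libraries and is no test. The interval of a median came from 500 Poisson redraws of the counts. Members were counted as 1.5-fold higher or lower among those with at least 30 counts in a library.

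Genes were named by a rule fixed before the data were examined. They had a CPM of at least 50, at least 30 counts and at least 10 cells with a UMI in the library where they were higher, and a class CPM of at least 0.5 times the CPM over all cells there. Of these, the 6 highest and 6 lowest by the ratio nearer to 0 in both contrasts were taken, and the 4 highest and lowest for the difference between genotypes. To these were added Vegfc, Flt4, Kdr, Nrp2, Cxcl12, Kitl and Cdkn1a and up to 4 genes per list. Mitochondrial, ribosomal, haemoglobin, immunoglobulin, sex-linked and unnamed predicted genes were left out of the ranking, and an unnamed transcript that the rule ranked among the lowest for deletion in endothelial cells is not described here. Not every gene that the rule ranked for irradiation is reported here. Adipoq, Ly6c1 and the marker genes of single clusters were outside this rule and were chosen after their values were seen. In the annotation used here (GRCm38), Flt4 lies on chromosome 11 (49609263 to 49652739), Kdr on 5 (75932827 to 75978458), Nrp2 on 1 (62703285 to 62818695), Cxcl12 on 6 (117168535 to 117181367), Kitl on 10 (100015630 to 100100416), Cdkn1a on 17 (29090976 to 29100727), Car3 on 3 (14863512 to 14872523), Fgf23 on 6 (127072902 to 127081408) and Aplnr on 2 (85136225 to 85139923).

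The comparisons were the cell class shares, Vegfc, irradiation within each genotype, deletion within each irradiation state, and the difference between the genotypes' irradiation responses. No test was made, since each group had 1 library, and cells were not used as replicates. A model with additive effects of genotype and irradiation, which would leave 1 residual degree of freedom among the libraries, was not fitted. The alternatives fixed beforehand were a looser filter (200 genes, 20% mitochondrial), a stricter filter (1000 genes, 5%), no doublet removal, resolutions of 0.5 and 2, TMM factors (edgeR 4.0.16 in R 4.3.3), totals without mitochondrial, ribosomal, haemoglobin and granule genes, the mean of per-cell CPM, a prior of 5 counts, no minimum and a minimum of 50 counts for list genes, cells thinned to 1500 UMIs, and shares over non-haematopoietic cells. Chosen after seeing the data were lists without genes below 0.5 times the all-cell CPM, and classes without the non-sinusoidal endothelial cluster and the shallowest LepR+ stromal cluster, called the doubted clusters.

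The calculation was tested on simulated counts with 200 planted genes per contrast. The counts were Poisson draws from the profile of a class pooled over the libraries, without differences between preparations or cells. Planted 2-fold changes came back with a median log2 size of 0.98 over 8615 endothelial and 0.99 over 9679 LepR+ stromal genes for irradiation in controls, of 1.00 over 9034 and 0.98 over 5950 genes for irradiation in Vegfc-deleted mice, of 0.98 over 8615 and 1.02 over 10425 genes for deletion without irradiation, and of 1.01 over 9979 and 0.95 over 5950 genes for deletion with irradiation. All planted changes had the right sign, and 86% to 100% of their intervals held the true value. Between 3% and 5.5% of 200 unchanged lists per contrast lay outside the random range, and each planted list lay at percentile 100. The unchanged lists were genes drawn at random, so that rate need not hold for lists of genes that vary together between preparations. The shallowest sum was that of LepR+ stromal cells in the irradiated Vegfc-deleted library, where Vegfc had 34 counts. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9.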

Results

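Single-cell RNA was sequenced from the tibial bone marrow of adult mice in 4 libraries, 1 for each combination of genotype and irradiation. Control mice carried floxed alleles of Vegfc, the gene for a secreted growth factor of blood and lymphatic vessels, and Vegfc-deleted mice carried the same alleles with a tamoxifen-inducible Cre recombinase at the Rosa26 locus. Irradiated mice received 4 Gy to the whole body and were sampled 7 days later. The non-irradiated libraries pooled 3 mice each and the irradiated libraries 2 mice each. Viable cells without lineage markers, CD45 and Ter119 were sorted before capture. The share of every cell class therefore describes the digested and sorted fraction, not the marrow, and for haematopoietic cells also how it was gated. Shares are relative, so a class can hold more of a library where other classes hold less. The libraries held 67370522 UMIs (non-irradiated control), 77284922 UMIs (non-irradiated Vegfc-deleted), 54462123 UMIs (irradiated control) and 64282090 UMIs (irradiated Vegfc-deleted). After filtering, 5058, 5211, 3837 and 4065 cells were kept in that order, with medians of 7635.5, 7851, 9874 and 9808 UMIs per cell. With 1 library per group there were no replicates and no test was made. Every interval is a 95% interval and covers counting error only, not differences between mice or preparations. Values of the 4 groups are given in the order above unless a sentence says otherwise.

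The first comparison asked which cell classes were recovered from each group. Endothelial cells, which line the marrow vessels, made up 6.09% of kept cells (5.45 to 6.78, exact binomial) in non-irradiated controls and 39.1% (37.5 to 40.7) in irradiated controls, a share 6.42-fold higher (5.68 to 7.28). In Vegfc-deleted mice the endothelial share was 7.22% (6.53 to 7.95) without and 17.4% (16.2 to 18.6) with irradiation, 2.41-fold higher (2.12 to 2.74). LepR+ stromal cells, the perivascular cells that supply most Cxcl12 and Kitl to haematopoietic stem cells, held 23.8% and 11.2% of the control libraries and 14.4% and 3.52% of the Vegfc-deleted libraries. Their share was thus 2.13-fold lower (1.91 to 2.38) with irradiation in controls and 4.09-fold lower (3.41 to 4.92) with irradiation in Vegfc-deleted mice. Osteolineage cells, which build bone matrix, were 9.85-fold more frequent after irradiation in controls (5.91 to 17.4) and 14.3-fold more frequent in Vegfc-deleted mice (6.61 to 36.7), from 17 and 7 cells without irradiation.

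Between genotypes, the endothelial share was 1.18-fold higher (1.02 to 1.38) in Vegfc-deleted mice without irradiation and 2.25-fold lower (2.06 to 2.47) with it. The LepR+ stromal share was 1.65-fold lower (1.51 to 1.81) and 3.17-fold lower (2.62 to 3.86) in Vegfc-deleted mice. Neutrophils, the short-lived granulocytes, were 3.41-fold more frequent in Vegfc-deleted mice without irradiation (2.85 to 4.08) and 9.32-fold more frequent with it (7.73 to 11.3), and made up 29.6% of the irradiated Vegfc-deleted library. Monocytes and macrophages were 3.04-fold (2.27 to 4.12) and 4.10-fold (3.44 to 4.90) more frequent there. T and NK cells were absent among the 5058 cells of the non-irradiated control, which allows a share of up to 0.0729%, and stood at 0.691%, 0.990% and 7.55% in the other libraries. B-lineage cells were 3.24-fold less frequent (2.65 to 3.99) in Vegfc-deleted than in control mice after irradiation. Erythroid cells held 41.2%, 42.5%, 13.9% and 10.0% of the kept cells, and basophils and mast cells 4.27%, 0.499%, 0.912% and 0.615%. Because these haematopoietic shares varied, the endothelial share was also taken among non-haematopoietic cells only, where it was 19.9%, 32.8%, 72.5% and 75.6%. On that scale the irradiated genotypes differed by a log2 ratio of 0.06, whereas over all cells the log2 ratio was -1.17. The LepR+ stromal share among non-haematopoietic cells was 77.8%, 65.2%, 20.7% and 15.3%, and the osteolineage share 1.10%, 0.610%, 6.14% and 8.35%.

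**Figure D1:**
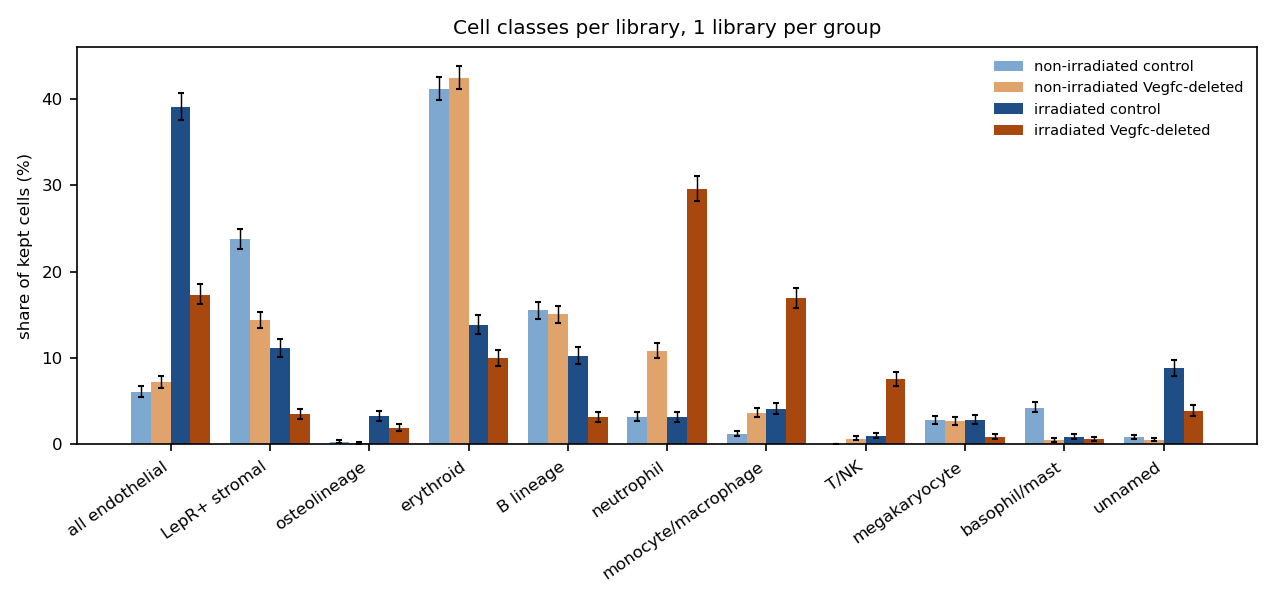
Share of kept cells (%, vertical axis) in 11 cell classes (horizontal axis) for the 4 libraries, with bars for 1 library each and black lines for exact 95% binomial intervals. Endothelial cells reached 39.1% in the irradiated control against 17.4% in the irradiated Vegfc-deleted library, where neutrophils held 29.6%.

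Vegfc itself was the first gene examined (ENSMUSG00000031520, GRCm38 chromosome 8, 54077606 to 54187096, plus strand). Among the recovered cells it was detected above background in LepR+ stromal cells. There it stood at 167.7 UMIs per 1000000 of the class (CPM, interval 160 to 176, exact Poisson) in non-irradiated controls. In non-irradiated Vegfc-deleted mice it stood at 17.6 CPM (14.6 to 21.2). That level was 9.50-fold lower in the deleted mice (7.87 to 11.6), a log2 ratio of -3.24 (-3.53 to -2.98) that was -3.81 when cells were thinned to 1500 UMIs. After irradiation the LepR+ stromal level was 178.9 CPM (167 to 192) in controls and 26.7 CPM (18.5 to 37.3) in Vegfc-deleted mice, 6.69-fold lower (4.75 to 9.73) and resting on 34 counts in the latter. Irradiation itself left the control level within a log2 ratio of 0.09 (-0.03 to 0.21). The remaining signal was carried by 7.61% and 11.2% of the LepR+ stromal cells of the Vegfc-deleted libraries, against 63.2% and 65.7% in controls, at median depths of 9256, 8716, 9707.5 and 7720 UMIs per cell. In erythroid cells, which should lack Vegfc, 0.53%, 0.05%, 0.38% and 0% of cells held a UMI at median depths of 7110, 9758.5, 9194 and 8573 UMIs. After thinning, 19.1%, 1.23%, 16.6% and 3.57% of LepR+ stromal cells held a Vegfc UMI. Endothelial cells held 1, 0, 14 and 0 Vegfc counts, in at most 0.53% of cells, so their expression was not separable from background at this depth. Most of these cells were sinusoidal and no cluster was named arterial, so Vegfc in arterial endothelium was not assessed.

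**Figure D2:**
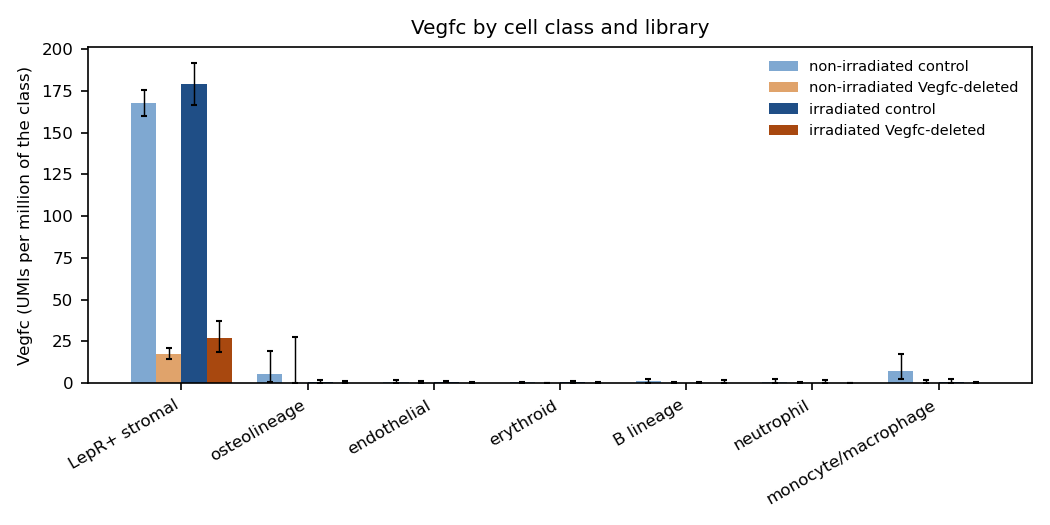
Vegfc level (UMIs per 1000000 of the class, vertical axis) in 7 cell classes (horizontal axis) of the 4 libraries, with bars for 1 library each and black lines for exact 95% Poisson intervals. LepR+ stromal cells stood at 167.7 and 178.9 CPM in the control libraries and at 17.6 and 26.7 CPM in the Vegfc-deleted libraries.

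Receptors of VEGF-C were measured in the endothelial class. Flt4, the receptor that VEGF-C binds with highest affinity (ENSMUSG00000020357), stood at 788, 600.2, 1019 and 832 CPM, so that it was lower in Vegfc-deleted mice, with log2 ratios of -0.39 (-0.48 to -0.31) without and -0.29 (-0.34 to -0.25) with irradiation. Kdr, the main receptor of VEGF-A, differed less, at 1536, 1358, 1807 and 1659 CPM, with log2 ratios of -0.18 and -0.12 between genotypes. Nrp2, a coreceptor for VEGF-C, stood at 491, 417, 636 and 532 CPM and was lower in Vegfc-deleted mice, at -0.24 (-0.34 to -0.13) and -0.26 (-0.31 to -0.20). Outside the endothelium, Nrp2 stood at 1255, 650, 1756 and 1301 CPM in osteolineage cells and at 226, 231, 193 and 183 CPM in LepR+ stromal cells. Among niche factors of LepR+ stromal cells, Cxcl12, the chemokine that retains stem cells in the marrow, stood at 24686, 22184, 22034 and 17408 CPM, a log2 ratio between genotypes of -0.15 without and -0.34 (-0.36 to -0.32; -0.19 when thinned) with irradiation. Kitl, the stem cell factor, was at 2138, 2115, 2635 and 1998 CPM, with -0.02 and -0.40 (-0.46 to -0.34; -0.19 when thinned) between genotypes.

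The irradiation comparison asked how endothelial and stromal cells differed 7 days after 4 Gy, in each genotype separately. In the endothelial class, genes induced by p53 after DNA damage were higher with irradiation in both genotypes. Phlda3, a brake on Akt signalling, stood at 11.2, 9.22, 116.5 and 107.7 CPM, log2 ratios of irradiated over non-irradiated of 3.36 (2.90 to 3.91) in controls and 3.53 (3.06 to 4.08) in Vegfc-deleted mice, with 2.62 in controls when cells were thinned. Zmat3, an RNA-binding regulator of splicing, was higher by 3.09 (2.63 to 3.63) and 2.72 (2.29 to 3.21), and Bax, a pore-forming effector of apoptosis, by 1.52 (1.35 to 1.69) and 1.62 (1.46 to 1.78). Eda2r, a death-inducing receptor, was higher by 5.19 (3.65 to 8.56) and 5.03 (3.47 to 8.41), from 2 counts in each non-irradiated library. Gdf15, a stress cytokine, was higher by 3.08 and 3.90. Cdkn1a, the cyclin-dependent kinase inhibitor that halts the cell cycle, differed between the genotypes. It was higher by 0.65 (0.59 to 0.72) in controls and near its non-irradiated level in Vegfc-deleted mice, at -0.12 (-0.19 to -0.05), or 0.14 when cells were thinned. Over the list of 20 p53 targets the median log2 ratio was 1.15 (0.94 to 1.36) and 0.57 (0.36 to 0.85), with 13 and 10 of 20 members at least 1.5-fold higher and 2 and 3 lower.

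Other endothelial genes were higher as well. Car4, a membrane-bound carbonic anhydrase, had 1 and 0 counts without irradiation and 992 and 429 with it, a level 177-fold higher (31.7 to 6992) in controls and at least 69.4-fold higher (lower limit of the interval) in Vegfc-deleted mice. Fn1, which encodes fibronectin, was higher by 6.37 (5.04 to 8.87) and 4.63 (3.98 to 5.46), where the first rests on 3 counts and was 4.41 without doublet removal, and the second was 2.90 when thinned and 6.22 without the non-sinusoidal cluster. Tgfa, a ligand of the EGF receptor, was higher by 2.49 and 2.69, and Fkbp11, a folding enzyme of the endoplasmic reticulum, by 2.23 and 2.48. Hmox1, which degrades haem, stood at 114, 82.5, 658 and 341 CPM. The interferon response list had medians of 0.81 (0.65 to 0.97) and 0.71 (0.60 to 0.85), with 11 and 10 of 16 members at least 1.5-fold higher and none lower. Its antiviral genes Ifit3 and Ifit1 were higher by 1.58 and 1.38 in controls and by 1.14 and 0.68 in Vegfc-deleted mice. Antigen presentation genes had medians of 0.69 and 0.47, which lay within the random range in at least 1 genotype when thinned (0.49 and 0.38) and when limited to genes at 0.5 times the all-cell CPM or more (0.37 and 0.23). Among them were Cd74 and H2-Aa, class II genes abundant in B and myeloid cells, at 2.90 and 2.56 in controls and 1.92 and 1.57 in Vegfc-deleted mice.

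Lower in irradiated endothelial cells of both genotypes were genes of the immediate early response, which cells switch on within minutes of a stimulus, including the handling of tissue. The list median was -1.11 (-1.14 to -1.09) in controls and -2.21 (-2.24 to -2.13) in Vegfc-deleted mice, with 12 and 16 of 16 members at least 1.5-fold lower. Egr1, a transcription factor of this response, stood at 4064, 3629, 989 and 243 CPM, and Atf3, a stress-induced repressor, at 437, 296, 79.1 and 9.79 CPM. Among the genes that were lowest in both genotypes, the growth arrest gene Gadd45b had log2 ratios of -3.26 and -5.54 (-7.85 when thinned), the secreted glycoprotein gene Stc1 -3.08 and -4.90, and the immediate early factor Egr3 -2.66 and -4.46 (-3.26 and -5.50 without the non-sinusoidal cluster). The small GTPase gene Gem had -2.72 and -3.42, or -3.03 and -4.68 when thinned, and the Ras exchange factor gene Rasgef1b -2.91 and -2.68. Inflammation and adhesion genes had medians of -0.46 and -0.26 (-1.19 and -0.93 when thinned, -0.98 and -1.29 with genes at 0.5 times the all-cell CPM or more), with Nfkbia, the inhibitor of NF-kB, at -2.39 and -2.71, and Sele, the selectin that captures leukocytes, at 510.4, 396.6, 84.0 and 116.9 CPM. Hypoxia and glycolysis genes (medians -0.52 and -0.33) included Ldha at -0.82 and -1.03, Ndrg1 at -0.66 and -1.20 and Vegfa, outside that list, at -1.42 and -1.77. The TGF-beta and BMP response list had medians of -0.62 and -0.48, with its feedback genes Skil at -1.62 and -1.45 and Smad7 at -1.54 and -0.99.

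The cell cycle list of the endothelial class was higher, at 0.97 and 1.26, but this rested on its non-sinusoidal cluster (8, 25, 115 and 44 cells). There Mki67, a marker of cycling cells, stood at 0, 56.7, 483 and 409 CPM, whereas the sinusoidal clusters had 40.9, 34.1, 10.7 and 8.18 CPM. Without that cluster the list medians were -0.39 and -0.47. The same cluster held granule transcripts of neutrophils at 159, 1536, 20797 and 56344 CPM, against 135, 369, 121 and 813 CPM in the sinusoidal clusters. In it, 0, 1, 6 and 28 cells held 10 or more granule UMIs, and 1, 2, 33 and 21 held 10 or more cell cycle UMIs. Whether the same cells held both, and whether they were joined with neutrophils, was not tested. The haemoglobin and granule list, a measure of RNA from other cells, was at 0.72 and 0.75 with the cluster and at -1.45 and -0.47 without it. Sinusoidal identity genes had list medians of 0.04 and 0.08, with Stab2, a scavenger receptor, at 0.08 in controls and 0.59 in Vegfc-deleted mice. Those sinusoidal cells nevertheless fell in different clusters, since 1 cluster held 289, 303, 5 and 1 of them and another 11, 48, 1380 and 661. Lists of extracellular matrix genes (0.10 and -0.06) and apoptosis genes (0.12 and 0.05) had medians near 0. Haematopoietic niche factors had medians of 0.01 and -0.15, the second outside the random range (-0.12 when thinned). The median log2 ratio of all genes was 0.19 and 0.14, and 0.02 and -0.02 with TMM factors.

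**Figure D3:**
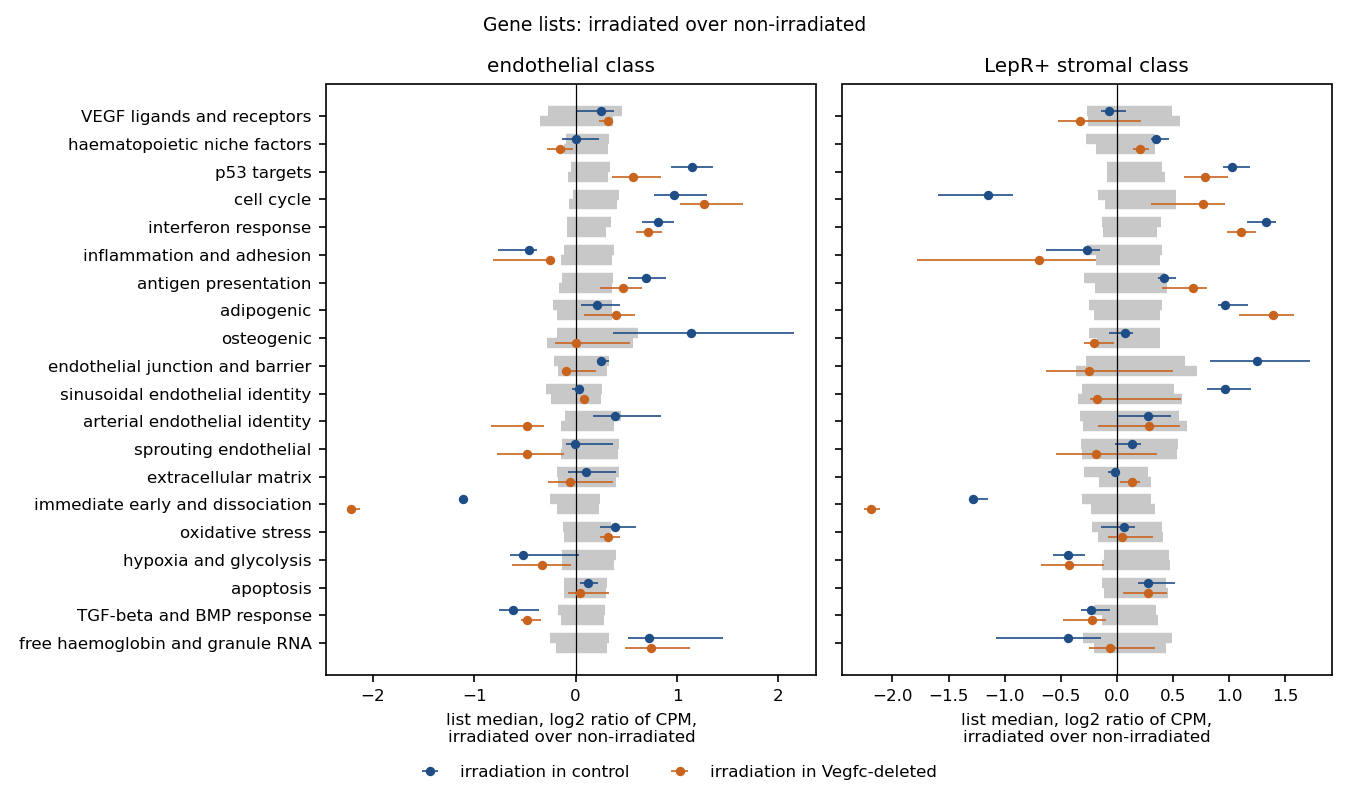
Median log2 ratio of CPM, irradiated over non-irradiated (horizontal axes), of 20 gene lists (vertical axis) in the endothelial and LepR+ stromal classes, with blue points for control mice, orange points for Vegfc-deleted mice, thin lines for 95% counting intervals and grey bars for the range from the 2.5 to the 97.5 percentile of random lists. In the endothelial class p53 targets lay at 1.15 and 0.57 and immediate early genes at -1.11 and -2.21.

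In LepR+ stromal cells, irradiation was accompanied by higher fat-cell genes in both genotypes. Fabp4, the fatty acid binding protein of adipocytes, stood at 64.3, 68.0, 2447 and 4380.0 CPM, log2 ratios of 5.25 (5.14 to 5.36) and 6.01 (5.87 to 6.15). Car3, a carbonic anhydrase abundant in adipocytes, stood at 3.06, 4.72, 1028 and 1268 CPM, log2 ratios of 8.37 (7.90 to 8.92) and 8.05 (7.56 to 8.63), which were 9.75 and 9.77 at clustering resolution 2, while the first was 7.40 when thinned and the second 7.33 without doublet removal. Plin1, which coats lipid droplets, had 0 and 1 counts without irradiation and 195 and 95 with it. Cd36, a fatty acid transporter, was higher by 3.12 (2.87 to 3.38) and 4.76 (4.34 to 5.23), and Adipoq, the adipocyte hormone that also marks LepR+ cells, by 0.84 and 0.58. The adipogenic list had medians of 0.96 (0.90 to 1.17) and 1.39 (1.08 to 1.58), or 0.87 and 0.91 when thinned, with 11 of 14 and 7 of 13 members at least 1.5-fold higher and 1 and 2 lower, Cebpb among the latter at -1.41 and -2.68. Other genes among the highest in both genotypes were the cholesterol exporter Abcg1 at 6.34 and 5.25 (3.46 in Vegfc-deleted mice when thinned), the adipocyte protein Arxes2 at 4.26 and 5.01, the fatty acid carrier Fabp5 at 3.70 and 5.89, the amine oxidase Aoc3 at 3.77 and 3.04 and the immune surface protein Cd83 at 2.97 and 2.78 (1.77 when thinned).

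The p53 targets and interferon genes were higher in LepR+ stromal cells as well. Medians of p53 targets were 1.02 (0.94 to 1.18) and 0.79 (0.59 to 0.99), with Ccng1, a cyclin that feeds back on p53, at 2.01 and 2.35 and Cdkn1a at 1.18 (1.11 to 1.25) and 0.79 (0.68 to 0.89). Interferon response medians were 1.33 (1.16 to 1.41) and 1.11 (0.98 to 1.24), with 15 and 14 of 16 members at least 1.5-fold higher, among them Ifit1 at 2.32 and 1.90 and Ifit3 at 2.14 and 1.69. Cxcl9, an interferon-induced chemokine for T cells, stood at 266, 339, 1867 and 1091 CPM. Angpt1, a ligand that steadies endothelial cells, was higher by 1.55 and 1.18, and Il15, a cytokine for NK cells, by 1.00 and 1.25.

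Ibsp, Mgp and Wisp2 were among the genes ranked lowest in irradiated LepR+ stromal cells, most of which fell in another cluster than the non-irradiated ones. The osteogenic list as a whole had medians of 0.07 and -0.20 (0.22 for the second when thinned), and the extracellular matrix list -0.02 and 0.13. Ibsp, which encodes bone sialoprotein, stood at 6461, 7137, 745 and 1087 CPM, with log2 ratios of -3.12 (-3.17 to -3.07) and -2.71 (-2.79 to -2.64). Mgp, an inhibitor of mineral deposition, was lower, at -4.36 and -2.95, which were -3.17 and -2.24 with the stricter cell filter, -2.99 and -2.27 at clustering resolution 0.5 and -4.72 and -2.40 when thinned. Wisp2, a matricellular protein gene, was at -4.36 and -2.91, and Angptl1, an angiopoietin-like factor, at -3.09 and -3.55. Ibsp and Wisp2 were leading markers of the cluster that held 1059, 611, 27 and 14 LepR+ stromal cells, whereas a cluster led by Lpl and Adipoq held 5, 4, 378 and 119. Immediate early genes had medians of -1.28 and -2.19, with Atf3 at -3.38 and -5.14 and Nr4a1, an orphan nuclear receptor, at -2.28 and -5.41. Vegfa was lower, at -0.80 and -2.06, as were Bmp6, a bone morphogenetic protein, at -1.20 and -1.88, and Nfkbia at -2.55 and -2.63. Medians of the hypoxia and glycolysis list were -0.44 and -0.42 and those of the TGF-beta and BMP list -0.23 and -0.22. The TGF-beta and BMP list no longer lay outside the random range in both genotypes with the looser cell filter, as the mean of per-cell CPM or when thinned. Haemoglobin and granule RNA in these cells was at -0.44 and -0.06. The all-gene median was 0.17 and 0.16.

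Across genes, the irradiation log2 ratios of the genotypes, which share no library, had a Pearson r of 0.78 and a Spearman rho of 0.64 over 10133 endothelial genes. Of the 954 and 964 endothelial genes at least 2-fold different, 599 were so in both genotypes and 595 of these had the same sign. In LepR+ stromal cells r was 0.67 over 10255 genes, and 513 of 520 shared genes had the same sign. Genes are not independent replicates. Of the 20 fixed lists, 9 in the endothelial and 6 in the LepR+ stromal class lay outside the 2.5 to 97.5 percentile range of random lists in the same direction in both genotypes. Among the 9, the cell cycle list did so in 8 of 14 alternatives and the haemoglobin and granule list in 5. Both changed sign without the non-sinusoidal cluster. The endothelial antigen presentation list did so in 12 of 14, and the LepR+ stromal TGF-beta and BMP list in 11.

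**Figure D4:**
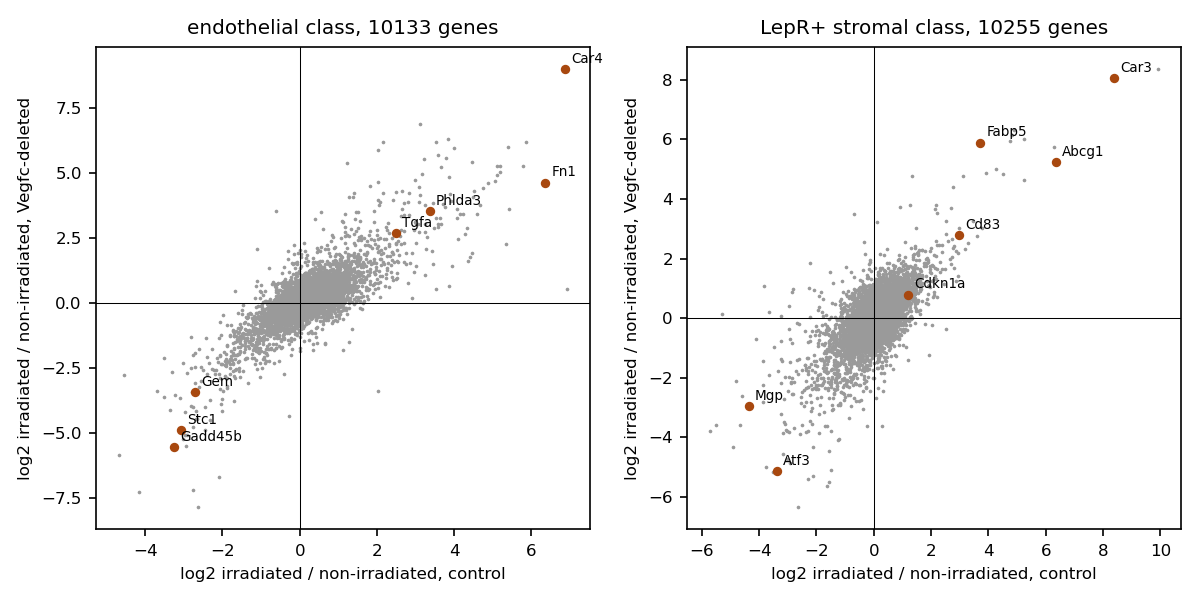
Log2 ratio of CPM, irradiated over non-irradiated, in control mice (horizontal axes) and Vegfc-deleted mice (vertical axes), with 1 grey point per gene for 10133 endothelial and 10255 LepR+ stromal genes and red points for labelled genes. Phlda3 lay at 3.36 and 3.53 in endothelial cells and Car3 at 8.37 and 8.05 in LepR+ stromal cells.

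The deletion comparison asked how the same cells differed between genotypes, without and with irradiation. In the endothelial class, Aplnr, the apelin receptor of sprouting and regenerating vessels, stood at 85.4, 31.9, 243 and 118 CPM. It was lower in Vegfc-deleted mice, with log2 ratios of -1.42 (-1.74 to -1.11) without irradiation, or -2.11 without the non-sinusoidal cluster, and -1.04 (-1.15 to -0.93) with irradiation. Fgf23, the hormone that controls phosphate, was higher at 132.0, 244, 124 and 253 CPM, log2 ratios of 0.88 (0.72 to 1.06; 0.55 with the stricter cell filter) and 1.03 (0.93 to 1.12). Cxcl9 was lower, at -1.37 (-1.51 to -1.23) and -0.92 (-0.98 to -0.86). Klf6, a stress-responsive transcription factor, stood at 1005, 559, 877 and 447 CPM, ratios of -0.85 (-0.93 to -0.77) and -0.97 (-1.03 to -0.91).

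Further genes with the same direction in both irradiation states were Igf1, an insulin-like growth factor (0.49 and 0.92), Thrsp, a regulator of lipid synthesis (0.49 and 0.62), Golgb1, a Golgi tether (0.67 and 0.48), Tia1, a stress granule protein (0.46 and 0.48), and Rtp4, an interferon-induced chaperone (0.61 and 0.43, or 0.12 and 0.58 when thinned). Lower in both were Phlda1, a growth-responsive regulator (-0.86 and -1.79, the second -1.30 when thinned), Trib1, a pseudokinase (-0.80 and -0.96, the first -0.52 when thinned), Plk2, a p53-responsive kinase (-0.79 and -1.29), and the BMP and growth factor responders Id1 (-0.52 and -0.70) and Cyr61 (-0.60 and -0.78). The interferon response list was higher in Vegfc-deleted endothelial cells, at 0.24 (0.17 to 0.35) and 0.36 (0.25 to 0.39), or 0.12 and 0.44 when thinned, where it no longer lay outside the random range in both states, with 5 of 15 and 5 of 16 members at least 1.5-fold higher and none lower. Ifit3 was higher by 1.04 (0.46 to 1.68) and 0.60 (0.40 to 0.81). The inflammation and adhesion list was lower, at -0.37 and -0.21 (-0.36 and -0.05 when thinned, no longer outside the random range in both states), and the sprouting list at -0.20 and -0.48 (-0.31 and -0.25 when thinned), the -0.20 near the edge of the random range. Neutrophil granule and haemoglobin transcripts, which come from other cells, were higher as well (1.66 and 1.05, or 0.63 and 0.84 when thinned), S100a9 among them by 1.80 and 1.71.

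In LepR+ stromal cells the interferon list was higher in Vegfc-deleted mice too, at 0.47 (0.41 to 0.62) and 0.46 (0.33 to 0.55), with 6 and 5 of 16 members at least 1.5-fold higher and none lower. With the stricter cell filter it no longer lay outside the random range in both states. Ifit3 stood at 13.4, 31.5, 59.1 and 101 CPM, log2 ratios of 1.23 (0.92 to 1.54) and 0.78 (0.46 to 1.09), and Rtp4 was higher by 0.76 (0.97 when thinned) and 0.65. Cish, an inhibitor of cytokine signalling, was higher, at 0.74 (0.53 to 0.95) and 1.19 (0.73 to 1.64), or 0.53 and 0.63 when thinned, as was Socs2, another such inhibitor, at 0.54 (0.44 to 0.65) and 0.91 (0.65 to 1.17; 1.24 when thinned). Arrdc3, an arrestin-like adaptor, was higher by 0.83 and 0.63 (1.59 when thinned), H2-Q6, a non-classical class I gene, by 0.59 and 0.66 (0.43 and 1.02 when thinned), and Sdc4, a heparan sulphate proteoglycan, by 0.80 and 0.58 (0.21 when thinned). Beside Vegfc itself, Serpina3n, a secreted protease inhibitor, stood at 204.5, 82.5, 92.6 and 44.8 CPM, log2 ratios of -1.31 (-1.45 to -1.17; -0.87 when thinned) and -1.04 (-1.47 to -0.64). Cxcl1, a neutrophil chemokine, was lower, at -0.97 (-1.07 to -0.86) and -1.23 (-1.79 to -0.75), or -0.75 and -2.35 when thinned. Gadd45b was lower, at -0.84 and -0.82 (-0.19 when thinned), Ier5l, an immediate early gene, at -1.07 and -0.84, and Egr3 at -0.85 and -4.83, the latter from 2 counts.

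The list of VEGF ligands and receptors was lower in LepR+ stromal cells of Vegfc-deleted mice, at -0.53 and -0.50 (-0.27 and -0.39 with genes at 0.5 times the all-cell CPM or more, -0.32 and -0.66 when thinned), with 3 and 4 of 9 members at least 1.5-fold lower. These were Vegfc itself, Adamts3 and Vegfd without irradiation and Vegfc, Vegfa, Pgf and Kdr with it, where the endothelial gene Kdr had 51 and 0 counts. The list thus holds the deleted gene, and its median without Vegfc was not computed. Vegfa, the main ligand of that family, moved in opposite directions, 0.59 (0.53 to 0.65) without and -0.68 (-0.91 to -0.45) with irradiation. The cell cycle list was at 0.16 and 2.36, the first of which was -0.27 when thinned. Granule and haemoglobin transcripts were higher by 1.5 and 1.4 in the same cells, with S100a9 at 54.6, 169.7, 44.9 and 361 CPM. Across genes, deletion log2 ratios of the irradiation states had a Pearson r of 0.29 over 8878 endothelial genes and 0.07 over 9788 LepR+ stromal genes. The Spearman rho was 0.29 and -0.012, and 61.1% and 48.6% of genes had the same sign. Of 31 endothelial and 23 LepR+ stromal genes at least 2-fold different in both states, 24 and 18 had the same sign. Genes ranked for deletion were required to have the same sign in both states, so their shared direction follows from the rule. In each class 4 of the 20 lists lay outside the random range in the same direction in both states, of which the endothelial sprouting list and the LepR+ stromal cell cycle list each did so in only 7 of 14 alternatives. The haemoglobin and granule list, a measure of RNA from other cells, was among the 4 in each class.

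**Figure D5:**
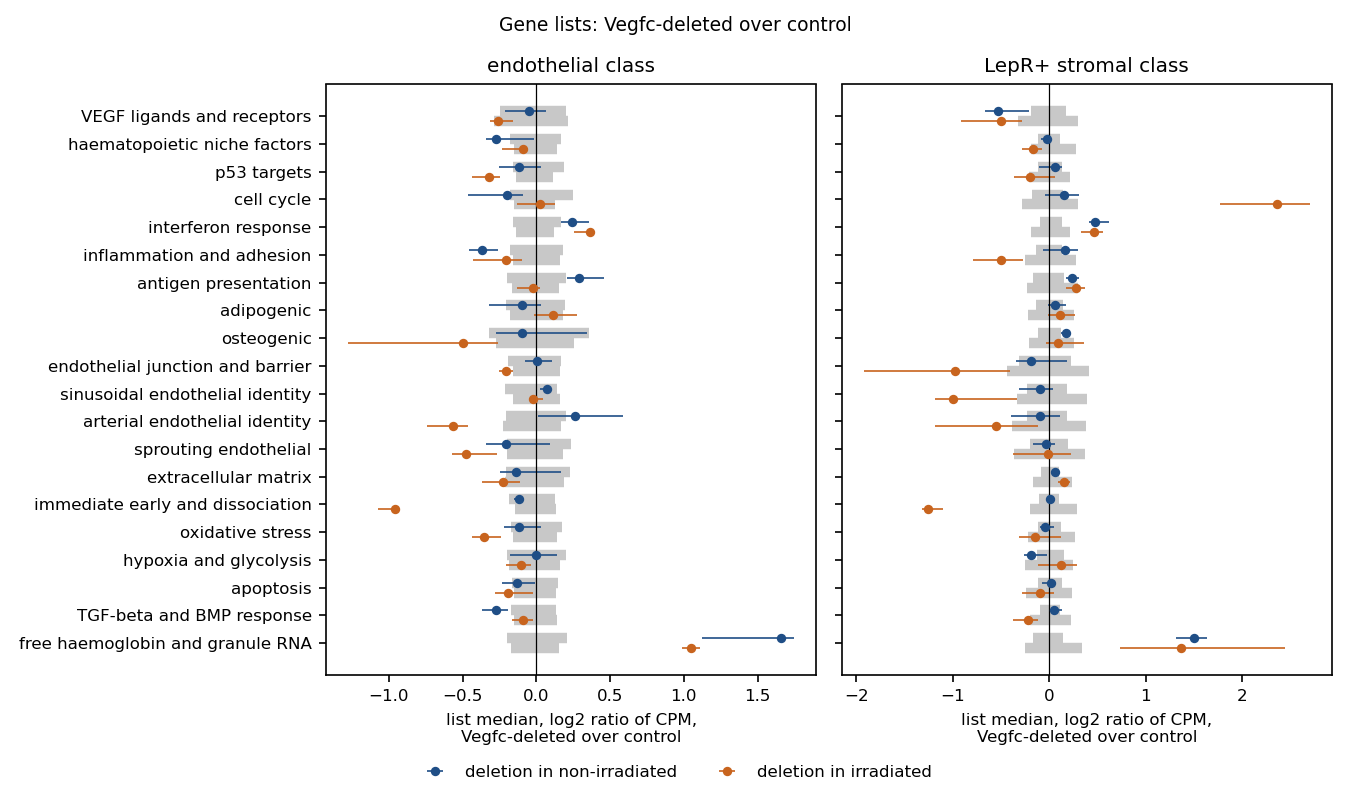
Median log2 ratio of CPM, Vegfc-deleted over control (horizontal axes), of 20 gene lists (vertical axis) in the endothelial and LepR+ stromal classes, with blue points for non-irradiated mice, orange points for irradiated mice, thin lines for 95% counting intervals and grey bars for the range from the 2.5 to the 97.5 percentile of random lists. Interferon genes lay at 0.24 and 0.36 in endothelial cells and at 0.47 and 0.46 in LepR+ stromal cells.

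The last comparison set the irradiation responses of the genotypes against each other, as the difference of the log2 ratios (Vegfc-deleted minus control). In the endothelial class, immediate early and stress genes had negative differences. Atf3 differed by -2.44 (-2.82 to -2.06), Gadd45b by -2.28 (-3.00 to -1.56; -4.53 when thinned), and Csrnp1, a nuclear factor induced by cytokines, at 363, 267, 113 and 19.8 CPM, by -2.06 (-2.35 to -1.77). Egr2, a related zinc finger factor, differed by -3.10 (-5.46 to -0.74), which rests on 1 count in the irradiated Vegfc-deleted library and was -1.21 with a prior of 5 counts. Over the list the difference was -0.87, with 13 of 16 members at least 1.5-fold lower. Cfd, the complement protease adipsin, stood at 262, 199.5, 81.4 and 273 CPM and differed by 2.14 (1.97 to 2.32), and Igfbp2, a carrier of insulin-like growth factors, by 1.97 (1.65 to 2.28). Car4 differed by 2.13 (-2.49 to 6.75), from 1 and 0 counts without irradiation and with 0.81 at a prior of 5 counts. Tagln, an actin-binding protein of contractile cells, differed by 1.66 (0.72 to 2.59) but by 0.16 without the non-sinusoidal cluster and -0.74 when thinned.

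Medians of p53 targets differed by -0.34, and Cdkn1a by -0.77 (-0.87 to -0.68). Antigen presentation genes differed by -0.32 (-0.21 when thinned, -0.17 with genes at 0.5 times the all-cell CPM or more, and outside the random range in 11 of 14 alternatives) and oxidative stress genes by -0.37, with Hmox1 at -0.48 (-0.71 to -0.25). Osteogenic genes differed by -1.28, led by the collagen gene Col1a1 at -2.65 (-3.47 to -1.83), which stood at 5.10, 13.7, 111 and 46.6 CPM and belongs to bone and stromal cells. That list lay outside the random range in 12 of 14 alternatives, but not without doublet removal or with genes at 0.5 times the all-cell CPM or more. Arterial identity genes differed by -0.94 (-0.44 when thinned, and within the random range without the non-sinusoidal cluster), among them Ly6c1, a marker of arterial and capillary endothelium, at -1.55 (-1.80 to -1.29). Sprouting genes differed by -0.35, or 0.36 when thinned, although Aplnr was higher after irradiation in both genotypes, by 1.51 (1.33 to 1.69) and 1.88 (1.61 to 2.18). Cell cycle genes differed by 0.29 and haemoglobin and granule RNA by -0.51 (-1.59 when thinned), but by -0.13 and 0.80 without the non-sinusoidal cluster. Of the 20 lists, 9 lay outside the random range, and these 2 were among them.

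In LepR+ stromal cells the immediate early list differed by -1.17, with 12 of 16 members at least 1.5-fold lower. Egr3 differed by -3.98 (-5.78 to -2.18), Csrnp1 by -3.60 (-5.42 to -1.77), A2m, a protease inhibitor, by -3.16 (-5.02 to -1.30) and Nr4a3, an orphan nuclear receptor, by -3.69 (-6.05 to -1.32), each from 1 or 2 counts in the irradiated Vegfc-deleted library. When thinned, Csrnp1 differed by -0.97 and Egr3 by -2.37, and with a prior of 5 counts A2m by -1.84 (-5.27 with the stricter cell filter) and Nr4a3 by -1.86. Tpm2, a tropomyosin, differed by 2.89 (2.48 to 3.29; 2.31 when thinned) and Tagln by 2.53 (1.99 to 3.07; 3.61 with the looser cell filter). Timp1, an inhibitor of matrix proteases, differed by 2.25 (1.73 to 2.76; 1.46 with the stricter cell filter) and Fabp5 by 2.18 (1.71 to 2.66; 1.28 when thinned). The cell cycle list differed by 2.07 (1.41 to 2.56), with Top2a, a topoisomerase of dividing cells, at 16.9, 25.1, 5.84 and 73.1 CPM. That list no longer lay outside the random range with genes at 0.5 times the all-cell CPM or more. Its irradiation median in Vegfc-deleted mice was -0.11 as the mean of per-cell CPM. Only 42, 19, 8 and 3 LepR+ stromal cells held 10 or more cell cycle UMIs. Haemoglobin and granule RNA in the LepR+ stromal class differed by 0.63 (0.31 when thinned). Endothelial junction genes, which LepR+ cells should lack, differed by -1.66, or -0.16 with genes at 0 counts set at the floor of 3 counts, and sinusoidal identity genes by -0.51, or -0.17 when thinned, and within the random range both then and with genes at 0.5 times the all-cell CPM or more. Of the 20 lists, 5 lay outside the random range, and the irradiated Vegfc-deleted library held 143 LepR+ stromal cells.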

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

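The tests of free RNA at the haemoglobin and granule shares, and the lists and classes named as added, were chosen only after the results were seen. Each result in this part stood out because a gene list moved in opposite directions in the groups compared. In every case the difference was not tested, since each group had 1 library.

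Cell cycle genes in LepR+ stromal cells had a median log2 ratio, irradiated over non-irradiated, of -1.15 in controls and 0.77 in Vegfc-deleted mice, with Mki67 at 44.8, 45.2, 6.97 and 40.1 CPM in the 4 libraries, but the second was -0.11 as the mean of per-cell CPM. Few of the cells held 10 or more cell cycle UMIs, namely 42 of 1202, 19 of 749, 8 of 428 and 3 of 143. Stromal cells joined with haematopoietic cells stay open, because leaving out stromal cells with at least 3 leukocyte UMIs, which gave a difference of medians of 2.02 against 2.07, removed only 4.40% and 2.09% of the list's UMIs in the irradiated libraries and could not find erythroid cells, so the bound set for it was ill chosen. Subtraction of free RNA scaled by haemoglobin and granule transcripts gave a difference of medians of 4.63, but this decides nothing and its bound was ill chosen, since the subtraction left 44.4% of the list genes at 0 in at least 1 library. Free RNA stays open, since at the share given by haemoglobin transcripts it would bring 143% of the gap in the summed list level between the irradiated libraries (224 and 564 CPM) but also 101.8%, 151% and 107% of the measured level in the other libraries than the irradiated control, and at the share given by granule transcripts 3.48% of the gap. A difference between genotypes in stromal cycling was not tested and stays open.

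Arterial identity genes in endothelial cells, Vegfc-deleted over control, had a median of 0.26 without and -0.57 with irradiation, with Ly6c1 at 0.85 and -0.70, and the first was -0.29 without the non-sinusoidal cluster. Inflammation and adhesion genes in LepR+ stromal cells, Vegfc-deleted over control, had a median of 0.16 without and -0.50 with irradiation, the first -0.034 with no minimum count, with the monocyte chemokine Ccl2 at 0.29 and -1.79 and the T cell chemokine Cxcl10 at -0.21 and -1.40.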

How the results depend on the processing

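The lists limited to genes at 0.5 times the all-cell CPM or more, and the classes without the doubted clusters, were chosen only after the results were seen, and every other alternative before. No paired analysis was possible because each group had 1 library, and no test was made that an alternative could end. Of the values recomputed, 19 of 20 for Vegfc, 1152 of 1367 medians of lists outside the random range, 1723 of 1958 for named genes and 39 of 47 shares stayed within their counting intervals, 78 of 84 numbers of lists stayed within 1.5-fold, and 43 list medians, 8 genes and 1 share changed sign. The lists of p53 targets, interferon response, immediate early genes and hypoxia lay outside the random range after irradiation in both classes and genotypes under all 14 alternatives, and the VEGF list in LepR+ stromal cells after deletion under all 14. That VEGF list holds the deleted gene Vegfc itself, and no alternative left Vegfc out. The interferon list after deletion did so in 13 of 14 in each class, with the exception of thinning in endothelial and the stricter filter in LepR+ stromal cells. Depth limited values of the irradiated Vegfc-deleted library, which held 143 LepR+ stromal cells and 34 megakaryocytes. Except where the construction is named, the cause was not tested.

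Shares taken over non-haematopoietic cells leave out the haematopoietic cells that differed between libraries. The log2 ratio of the endothelial share was then 1.86 for irradiation in controls and 0.061 for deletion with irradiation, against 2.68 and -1.17 over all cells, and that of the LepR+ stromal share was -1.91 for irradiation in controls and -0.25 and -0.43 for deletion without and with irradiation, against -1.09, -0.73 and -1.66. The endothelial share for irradiation in Vegfc-deleted mice was 1.47 with the looser filter against 1.27, and the neutrophil share for deletion with irradiation 2.89 at resolutions 0.5 and 2 against 3.22. Vegfc in LepR+ stromal cells without irradiation was -3.81 when thinned against -3.24. The number of lists outside the random range for deletion in endothelial cells was 7 with the looser filter, 7 with no doublet removal and 1 when thinned, against 4, and for the difference between genotypes in LepR+ stromal cells 8 with the stricter filter, 8 with no doublet removal and 2 with genes at 0.5 times the all-cell CPM, against 5.

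Values that changed sign are given by setting, with irradiation in controls, irradiation in Vegfc-deleted mice and their difference as C, D and D minus C. In the endothelial class with the looser filter, the cell cycle list was -0.75 (C), -0.46 (D) and -0.036 (D minus C), the free haemoglobin and granule list -1.52, -0.51 and 0.62, the arterial list -0.27 for deletion without irradiation, Kitl -0.72 (C) and Cxcl12 0.23 (D minus C). Without the doubted clusters, which removes the non-sinusoidal cells, the same values were -0.39, -0.47 and -0.13, then -1.45, -0.47 and 0.80, then -0.29, -0.80 and 0.34. The free haemoglobin and granule list was -1.52, -0.46 and 0.53 at resolution 0.5 and -1.52, -0.46 and 0.53 at resolution 2, -0.79, -0.43 and 0.17 with no doublet removal, -1.56 (C) and 1.39 (D minus C) with the stricter filter, and -0.14 (D) as the mean of per-cell CPM. When thinned, the arterial list was -0.14 for deletion without irradiation, the sprouting list 0.36 (D minus C), Cdkn1a 0.14 (D) and Tagln -0.74 (D minus C). The cell cycle list was -0.63 (D minus C) with genes at 0.5 times the all-cell CPM, and the osteogenic list -0.0016 (C) with a prior of 5 counts.

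In the LepR+ stromal class, the cell cycle list for deletion without irradiation was -0.27 when thinned, -0.0807 as the mean of per-cell CPM, -0.13 with no doublet removal and -0.048 without the doubted clusters, and it was -0.11 (D) as the mean of per-cell CPM. The endothelial junction list was -0.60 (C), 0.12 for deletion with irradiation and 0.24 (D minus C) with genes at 0.5 times the all-cell CPM, which leaves out genes whose level is higher in other cells, and 0.031 (D minus C) when thinned. The osteogenic list (D) was 0.22 when thinned and 0.11 as the mean of per-cell CPM, and Kitl (D) 0.16 and 0.043. The inflammation list for deletion without irradiation was -0.034 with no minimum count, and the VEGF list (D) 0.18 with a prior of 5 counts.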

Other observations

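Of the tests in this part, the haemoglobin-scaled subtraction for interferon genes was chosen only after the result was seen, and the others before. Other cell classes also carried p53 target genes after irradiation, at very different levels. In megakaryocytes, the platelet-forming cells (141, 139, 109 and 34 cells), Cdkn1a stood at 9.26, 11.9, 1123 and 332 CPM and Phlda3 at 18.5, 39.8, 448 and 197 CPM in the 4 libraries. Their p53 list had median log2 ratios of 2.96 in controls and 1.06 in Vegfc-deleted mice, their interferon list 2.08 and 1.76, and their cell cycle list -3.97 and -3.40. Erythroid cells had p53 list medians of 1.07 in each genotype, with Cdkn1a at 5.05, 4.49, 94.0 and 32.1 CPM. Not every member was higher, as the apoptosis gene Bbc3 stood at 69.4, 32.7, 32.9 and 9.23 CPM. The erythroid cells also fell in different clusters, of which 1 held 342, 345, 5 and 8 cells. In B-lineage cells the p53 list was lower, at -0.54 and -0.45, with Trp53inp1, a p53-induced stress protein, at 203, 220.2, 129.5 and 103 CPM, whereas Ccng1 was higher, at 28.2, 33.5, 48.3 and 58.5 CPM, as were Bax and Zmat3. Cell cycle genes were higher in B-lineage cells by 1.17 and 0.84, but the cells also fell in different clusters, of which 1 held 275, 213, 15 and 3 cells and another 45, 77, 256 and 97. Neutrophils had p53 medians of 0.09 and -0.15, with Cdkn1a at 61.5, 46.1, 38.4 and 19.5 CPM and Trp53inp1 at 27.3, 39.1, 82.4 and 54.7 CPM.

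An unnamed cluster occurred only with irradiation in these libraries (0, 0, 109 and 8 cells). Its leading genes included Bbc3, the apoptosis gene also called Puma, and Trp53inp1, and its closest markers were those of megakaryocytes, with a score of 2.13. Interferon genes were higher after irradiation in monocytes and macrophages, at 0.59 and 1.48, and in neutrophils, at 0.67 and 0.76, although the cells also fell in different clusters. A neutrophil cluster held 79, 289, 1 and 2 cells and another 0, 1, 62 and 479, and a monocyte and macrophage cluster held 6, 21, 53 and 318. Inflammation and adhesion genes were lower in Vegfc-deleted than in control mice in monocytes and macrophages (-0.52 without and -1.35 with irradiation), neutrophils (-0.86 and -0.90) and erythroid cells (-0.63 and -1.48). Values of B-lineage cells and megakaryocytes are not given here. Whether free RNA of other cells or handling contributed to this list was not tested.

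Immediate early genes were lower in the irradiated Vegfc-deleted than in the irradiated control library in endothelial (-0.96) and LepR+ stromal cells (-1.26). A handling or dissociation response shared by all cells of a library is a candidate explanation, since 4 of 5 haematopoietic classes had a list median below -0.3, namely B-lineage cells at -0.48, erythroid cells at -0.99, neutrophils at -0.36 and monocytes and macrophages at -0.53, while megakaryocytes stood at -0.0014. For the lower level after irradiation in controls, 3 of 5 classes lay below -0.3, whereas erythroid cells stood at 0.72 and megakaryocytes at 1.15, so the handling or dissociation response could not be separated from irradiation there. An effect of genotype or irradiation on these genes was not tested and stays open for both.

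Interferon genes were higher in Vegfc-deleted mice in endothelial and LepR+ stromal cells in both irradiation states. Free RNA of the library's other cells was subtracted at the share given by granule transcripts, and 4 of 4 list medians kept at least 0.5 of their value. They were 0.24 and 0.43 in endothelial and 0.48 and 0.46 in LepR+ stromal cells. The haemoglobin-scaled subtraction gave 0.19, 0.37, 0.47 and 0.36. At these shares free RNA would not bring the whole of the medians. The granule shares were only 0.627% to 1.38% in LepR+ stromal and non-irradiated endothelial cells. So little was taken away there that the granule-scaled outcome decides little. The shares are uncertain, since in irradiated Vegfc-deleted LepR+ stromal cells granule transcripts gave 0.742% and haemoglobin 13.8%. In irradiated endothelial cells the granule share was 9.94% in the control and 3.99% in the Vegfc-deleted library, so subtraction there could hardly lower the median. Granule transcripts there stood at 20797 and 56344 CPM in the non-sinusoidal cluster, against 121 and 813 CPM in the sinusoidal clusters. The share of the whole class is therefore no measure of free RNA spread evenly over its cells. Free RNA at another share stays open. A difference between preparations that act on all cells of a library may contribute, and with 1 library per group neither that nor an effect of Vegfc deletion was tested. The Cre recombinase was described for the Vegfc-deleted mice only, so its presence cannot be told apart from the loss of Vegfc in any comparison of genotypes.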
